A study of Homo sapiens with 6 samples.

How the data were processed

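The samples were 6 single-cell 3′ RNA libraries from primary human breast cells of 3 donors, 1 vehicle library and 1 octanoic acid library per donor. Octanoic acid is a medium-chain fatty acid and was given at 5 mM. Small pieces of breast tissue (microstructures) were exposed to vehicle or octanoic acid, and cells were left for 48 h to move out onto the plate. The cells were then released with trypsin, passed through a 40 µm strainer and loaded at 3400 viable cells per µL with an Illumina 3′ single-cell kit of the T10 size.

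The deposited matrices hold raw counts per gene and barcode, with no normalization, as whole numbers of at least 1. They were not filtered to called cells, and the barcodes in 1 library numbered 498981 to 716159. The deposited gene and barcode tables hold text of other kinds, with no measurement, and the 6 gene tables were identical, with 37468 genes. The authors' processing notes name GRCh38, R 4.4.0 and Seurat 5.3.1 without saying what each was used for. The aligner and the counting tool are not given in the sources used here, nor is it stated whether 1 count is 1 molecule, so the word count is used throughout.

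Each library was read on its own in python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5). A set of 132 genes (XIST and genes on the Y chromosome) was dropped first, which left 37336. A barcode was kept as a cell with at least 1000 counts, at least 500 genes and at most 20% mitochondrial counts. Its counts also had to reach 10% of the 99th percentile of the 10000 barcodes with most counts in that library, a threshold that came to between 1746 and 2669 counts. The mitochondrial limit removed 0 cells. The 5% of cells with the highest Scrublet scores were then removed as doublets in every library. This rule replaced Scrublet's automatic threshold after the data were seen, since that threshold called 2.89% to 6.7% of cells in the vehicle libraries and 0.02% to 0.22% in the octanoic acid libraries.

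Cells of all libraries were clustered together without correction for donor, from 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. A cluster of at least 200 cells could take the name of a cell type. At least 3 of that type's markers had to be at least 2-fold (log2 of 1) above the mean of the other clusters. In addition, no second type could have 60% or more of its own marker list raised as far. Other clusters stayed unnamed. There were 12 cell type marker lists and 28 gene lists for pathways and processes, all written before the data were examined, as were the tests, the rule for named genes and most alternatives. Class names carry "-like" because they rest on transcripts alone.

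The library was the replicate, so counts were summed over the cells of a library, and over the cells of a class within it, where every library had at least 50 such cells. Endothelial-like cells did not reach that number. Octanoic acid and vehicle were compared in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood fit with robust estimates, glmQLFTest). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The labels give the donors, which pair the libraries, but no model, so the fit without the donor was the main one. The count with donor as a replicate block is printed beside it. The main list tests and the fits of changed genes that leave out a library or a donor also ran without the block. The pairing was checked by correlating each library's deviation from its group mean across genes. Over all cells, the vehicle and octanoic acid libraries of 1 donor correlated at 0.498, 0.495 and 0.538, and these are correlations across genes, which are not independent replicates.

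Gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists. With an estimated correlation, no camera call was kept in any of the 6 comparisons. List members were counted by the edgeR test, adjusted over all genes tested and adjusted over the list alone. Whether a gene's response differed between 2 classes was tested by the class-by-treatment term of 1 edgeR model with library as a block. Shares of cells were compared by a two-sided exact permutation test over the 6 libraries, for which the smallest possible p is 0.1. Wilson intervals at 95% cover counting error only.

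CPM are counts scaled to the TMM-adjusted total of the tested genes. The genes named for each comparison were past the threshold, with a mean of at least 10 CPM in 1 group. They also had the same sign in all 3 donors. Of these, the 10 with the largest log2 fold change in each direction were taken for all cells, and 8 for a class. For each list described, up to 4 members with the smallest p were added, as were CPT1A, PDK4, ANGPTL4, PLIN2, PHGDH, PSAT1 and HES1 where tested. Another gene in that part of the rule is not reported here. Symbols were those of the deposited gene table. All 91 genes named by the first part of the rule, by name or in the class-by-treatment test were found by identifier in GENCODE release 29 (GRCh38).

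Counts from free RNA were bounded from barcodes with at most 100 counts. The level of genes foreign to a class (7 fibroblast genes, or 7 keratins for fibroblast-like cells), divided by their level in those barcodes, gave an upper estimate of 2.17% to 9.86% of a class's counts. The tests were run on simulated data made from these libraries with 200 changed genes. In all cells, edgeR found 78.1% of the 4-fold and 27.4% of the 2-fold changes, and in the classes 76.6% to 91.8% and 24.2% to 44.9%. Calls of unchanged genes numbered 9 of 110 in all cells and 15 of 137 in basal-like cells. With the donor block in edgeR they were 13 of 104 in all and 26 of 155 in fibroblast-like cells. DESeq2 made 63 of 197 such calls in all cells, and 89 of 222 with the block. The simulated data held no donor effect.

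The alternatives were the donor block, DESeq2 size factors in edgeR, DESeq2 1.42.0 with and without the block, no filter on low counts, a stricter cell filter (2000 counts, 1000 genes, 10% mitochondrial counts), doublets kept, equal numbers of cells, every barcode summed, cells assigned one by one, and leaving out each library or donor. Chosen after the data were seen were Scrublet's automatic calls, fixed floors without the library threshold, Leiden resolutions 0.5 and 2 for the gene comparisons, and leaving out the 2 libraries with most cells in clusters made mostly of the other group. The camera test of the class-by-treatment term was also added then. Figures were drawn with matplotlib 3.10.9.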

Results

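Breast tissue pieces from 3 donors were cultured with vehicle medium or with 5 mM octanoic acid, a saturated medium-chain fatty acid, and the cells that moved out over 48 h were profiled as single cells by their RNA. Each group had 3 libraries, 1 per donor. The deposited counts of the vehicle libraries 1 to 3 came to 76106746, 90346808 and 50067105. Those of the octanoic acid libraries 1 to 3 came to 63883000, 53835737 and 60949950. After filtering, the vehicle libraries held 8150, 15500 and 8260 cells with median counts per cell of 5853, 3240 and 3041. The octanoic acid libraries held 9619, 6459 and 6523 cells with medians of 3625, 3684 and 3840. Cells held 61.6% to 76.4% of a library's counts. The comparison asks which cell types and transcripts differ between cells that left the tissue with and without the fatty acid.

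Cells resembling basal (myoepithelial) cells, fibroblasts and the 2 luminal types of the breast made up most of every library, and fibroblast-like cells took a smaller share under octanoic acid. Their share averaged 37.9% ± 8.46 in vehicle and 14.4% ± 5.83 in octanoic acid (SD, n = 3). It was 36.3%, 47.0% and 30.3% in the vehicle libraries, with Wilson 95% intervals of 35.3% to 37.4%, 46.2% to 47.7% and 29.3% to 31.3%. In the octanoic acid libraries it was 20.9%, 12.9% and 9.55%, with intervals of 20.1% to 21.7%, 12.1% to 13.7% and 8.86% to 10.3%. The mean difference was -23.4 percentage points, and the share was lower in all 3 donors. The groups did not overlap, as chance gives in 10% of such comparisons (two-sided exact permutation p = 0.1, the smallest this test allows). The permutation takes no account of the pairing of libraries by donor. With the same count floor in every library the difference was -11.6 points, still lower in all 3 donors, but the groups overlapped (exact p = 0.2), with octanoic acid library 1 at 25.84% and vehicle library 3 at 24.69%.

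The shares of the other classes overlapped between the groups. Basal-like cells averaged 32.8% ± 12.3 in vehicle and 50.8% ± 19.5 in octanoic acid (exact permutation p = 0.3), with donor differences of 21.5, 33.9 and -1.40 points. With cells assigned one by one the means were 27.14% and 27.98%. By that assignment basal-like cells numbered 3697, 1821 and 1129 in octanoic acid libraries 1 to 3, against 6489, 3580 and 1916 by cluster. In vehicle libraries 1 to 3 they numbered 3069, 2895 and 2072, against 3745, 3343 and 2542 by cluster. Luminal secretory-like cells, the milk-producing lineage, averaged 17.9% ± 6.45 and 15.6% ± 6.97 (exact p = 0.7), with donor differences of -3.47, -3.90 and 0.460. Their direction turned at Leiden resolution 0.5 (18.2% and 18.77%) and with doublets kept (17.09% and 18.98%). Luminal hormone-sensing-like cells averaged 7.58% ± 6.45 and 13.7% ± 16.1 (exact p = 0.7), with donor differences of -2.14, 3.28 and 17.1. Endothelial-like cells averaged 1.02% ± 0.448 and 0.545% ± 0.146 (exact p = 0.2) and were lower in all 3 donors, with differences of -0.528, -0.765 and -0.137 points. With cells assigned one by one their mean difference turned to 2.494 points, higher in all 3 donors. Cells in clusters without a name averaged 2.91% ± 1.67 and 5.05% ± 4.02 (exact p = 0.4) and were higher in all 3 donors, by 0.0725, 1.63 and 4.73 points. This direction turned with fixed floors (-0.09 points), at Leiden resolution 0.5 (-1.341) and with doublets kept (-6.071).

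Within a class the cells of the 2 groups lay mostly in different clusters. Of 7 basal-like clusters, 4 were at least 90% vehicle cells and 3 at least 90% octanoic acid cells, and these held 98.6% of the vehicle and 99.1% of the octanoic acid basal-like cells. Of 7 luminal-like clusters 4 and 2 were such, with 96.9% and 92.7% of the cells, and of 5 fibroblast-like clusters 3 and 1, with 95.9% and 92.7%. The comparisons within a class below are thus between largely separate sets of clusters, and whether cells changed or other cells of the class came out of the tissue was not tested. Clustering had no correction for donor, and libraries of the vehicle group parted from each other as well. A fibroblast-like cluster held 5775 cells of vehicle library 2, against 56 and 88 of vehicle libraries 1 and 3.

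**Figure D1:**
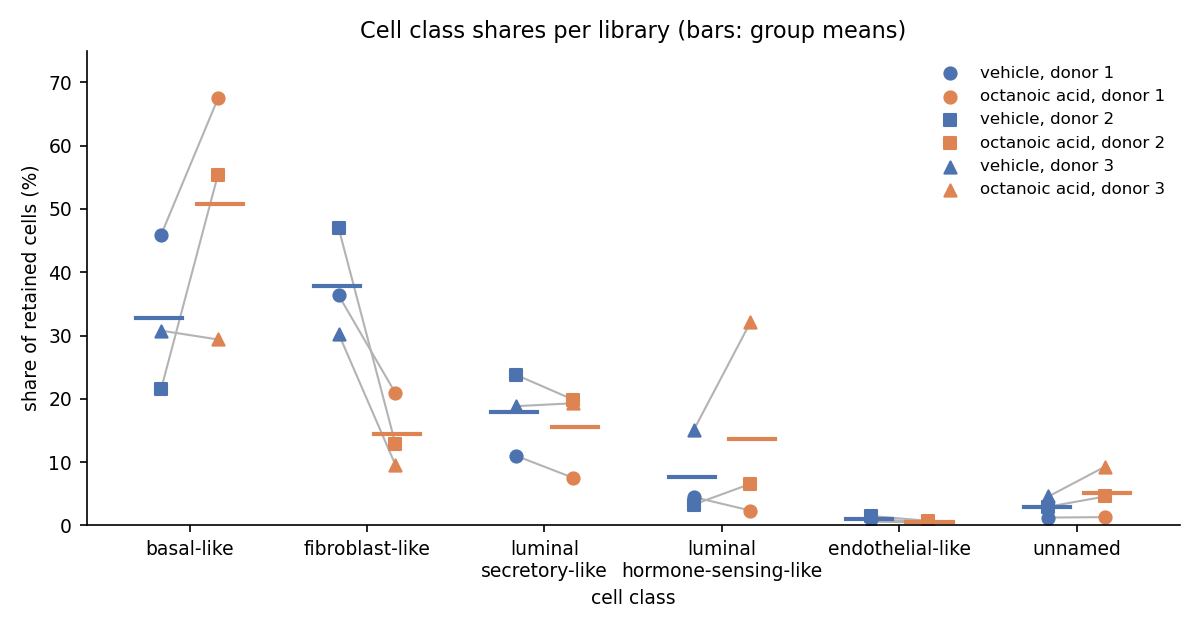
Share of retained cells (%) in each cell class, by group, with 1 point per library, lines joining the libraries of a donor and bars at the mean. The fibroblast-like share lies between 9.55% and 20.9% in octanoic acid and between 30.3% and 47.0% in vehicle.

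Summed over all cells, octanoic acid libraries held more of some transcripts of PPAR targets, fatty acid oxidation and stress, and less of most measured ones of cell division and connective tissue matrix. No list call below was kept by camera with an estimated correlation, in all cells or in a class. At the preset correlation, some other split of the libraries called as many lists or more, except in basal-like cells. CPM below are counts scaled to the TMM-adjusted total of the tested genes. PLIN2, which codes for a coat protein of lipid droplets, rose from 90.1 ± 39.8 to 604 ± 162 CPM (SD, n = 3). This was a log2 fold change of 2.75 ± 0.38 (SE, adjusted p = 0.00917). CPT1A, the carnitine transferase that admits long-chain fatty acids to mitochondria, rose from 22.4 ± 7.61 to 72.7 ± 11.8 (1.70 ± 0.26, adjusted p = 0.0124). CLGN, an endoplasmic reticulum chaperone, had the largest rise by the naming rule, from 2.32 ± 1.52 to 40.8 ± 14.9 (4.13 ± 0.53, adjusted p = 0.00802). GDF15, a cytokine made by stressed cells, went from 40.6 ± 38.2 to 439 ± 55.9 (3.43 ± 0.68, adjusted p = 0.0231). COL1A1, the main chain of type I collagen, fell from 1959 ± 375 to 79.0 ± 37.5 (-4.63 ± 0.42, adjusted p = 0.00485). MKI67, a marker of dividing cells, fell from 10.8 ± 4.87 to 0.451 ± 0.698 (-4.61 ± 1.11, adjusted p = 0.0399).

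On GRCh38, PLIN2 (ENSG00000147872) lies on chromosome 9 at 19108375 to 19149290 and CPT1A (ENSG00000110090) on chromosome 11 at 68754620 to 68844410. CLGN (ENSG00000153132) lies on chromosome 4 at 140388455 to 140427968, and GDF15 (ENSG00000130513) on chromosome 19 at 18374731 to 18389176. COL1A1 (ENSG00000108821) lies on chromosome 17 at 50183289 to 50201632 and MKI67 (ENSG00000148773) on chromosome 10 at 128096659 to 128126385. ANGPTL4 (ENSG00000167772) lies on chromosome 19 at 8363289 to 8374373, and PDK4 (ENSG00000004799) on chromosome 7 at 95583499 to 95596491. All are protein-coding genes in the annotation.

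Among the other genes chosen in advance, PHGDH, the first enzyme of serine synthesis, rose by 0.88 ± 0.20 (adjusted p = 0.0314), reaching 0.105 without some library. Log2 fold changes of ANGPTL4 (1.02 ± 0.31), PDK4 (1.24 ± 0.34), HES1 (0.55 ± 0.21) and PSAT1 (0.44 ± 0.17) did not pass, with adjusted p = 0.0740, 0.0558, 0.137 and 0.130. With the donor as a block these were 0.00714, 0.0154, 0.0372 and 0.0269. Further large rises were those of LRAT, which stores retinol as esters (3.22 ± 0.18), and the transporter SLCO4A1 (3.54 ± 0.26), and further large falls those of NOX4, an oxidase that makes hydrogen peroxide (-3.91 ± 0.38), and GSTA1 (-5.24 ± 0.61).

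**Figure D2:**
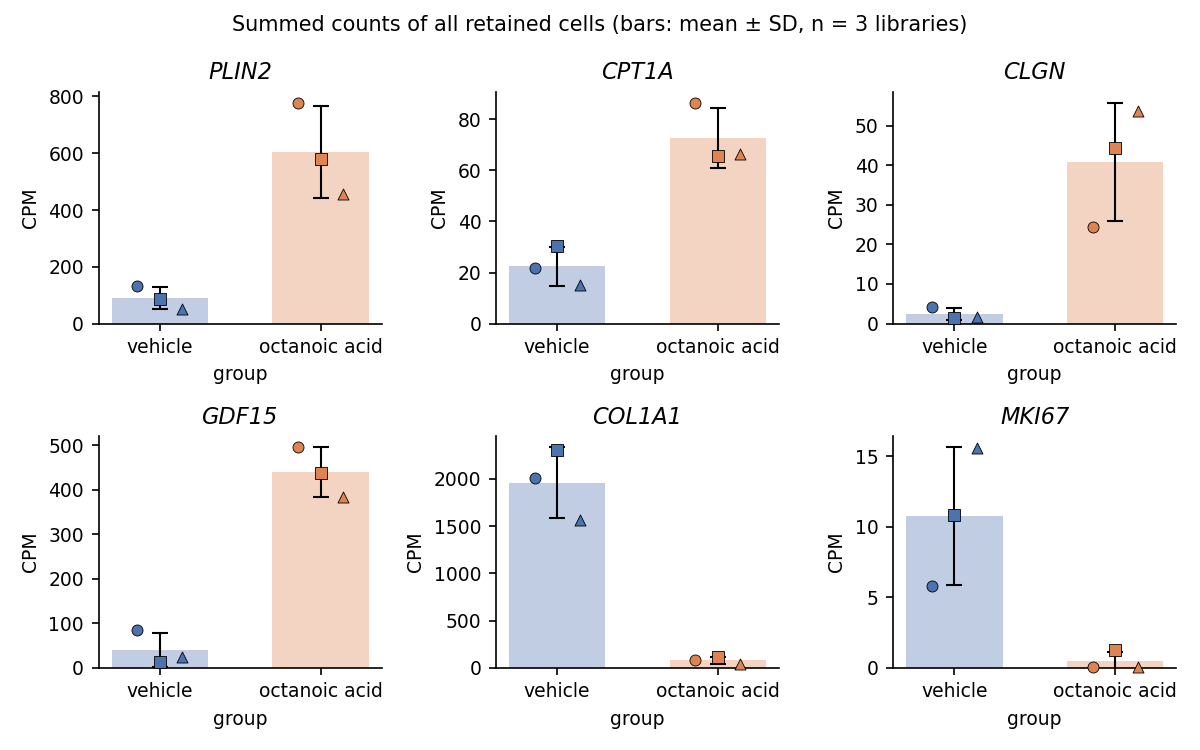
CPM of 6 genes in the summed counts of all retained cells, with 1 point per library and bars at the mean ± SD (n = 3 libraries per group). PLIN2 averages 90.1 in vehicle and 604 in octanoic acid, and COL1A1 1959 and 79.0.

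Of 33 measured genes of the list of PPAR targets and fatty acid oxidation, 9 rose and 1 fell (16 and 2 adjusted over the list alone). Values given for list members are log2 fold changes ± SE. Among those that rose were ACADVL, which starts the oxidation of very long fatty acids in mitochondria (1.08 ± 0.11), and ACSL1, which activates fatty acids (1.77 ± 0.28). The list was higher by camera (adjusted p = 0.000266, and adjusted p = 0.232 with an estimated correlation). Adipocyte markers moved with it, 4 of 8 rising and 1 falling (camera adjusted p = 0.0227, and adjusted p = 0.379 with an estimated correlation), with PLIN4 at 1.72 ± 0.35 and LPL at -1.42 ± 0.22. No cluster took the adipocyte name. Cells assigned one by one to it made up 0.896%, 0.787% and 0.908% of the vehicle and 8.60%, 6.18% and 4.23% of the octanoic acid libraries. A rise by this assignment was not particular to that name. Cells assigned one by one as endothelial made up 1.86%, 2.37% and 1.21% of the vehicle and 4.68%, 5.22% and 3.04% of the octanoic acid libraries. In the list of ATF4 targets, genes of amino acid supply and the integrated stress response, 9 of 24 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 7.92e-06, and adjusted p = 0.311 with an estimated correlation). ATF3 was at 1.30 ± 0.19 and the amino acid transporter subunit SLC3A2 at 1.12 ± 0.17. Of 19 genes of fatty acid synthesis 6 rose, among them FADS1 at 1.42 ± 0.18, and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00594, and adjusted p = 0.503 with an estimated correlation). In cholesterol biosynthesis 1 of 23 rose, STARD4 at 2.14 ± 0.38, and 7 did so adjusted over the list alone (camera adjusted p = 0.000204, and adjusted p = 0.547 with an estimated correlation). The antioxidant NRF2 list had 5 of 27 genes rising and 0 falling (7 and 0 adjusted over the list alone, camera adjusted p = 0.000428, and adjusted p = 0.379 with an estimated correlation). SRXN1 was at 1.44 ± 0.17.

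Genes of cell division fell together: 28 of 32 were lower and 0 higher (30 and 0 adjusted over the list alone), with the replication factor MCM6 at -1.77 ± 0.18 and the mitotic activator CDC20 at -3.38 ± 0.41. This list had a camera adjusted p of 2.86e-24 and an adjusted p = 0.311 with an estimated correlation. In the list of p53 targets, which act in cell-cycle arrest among other roles, 5 of 24 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0138, and adjusted p = 0.547 with an estimated correlation). MDM2 was at 1.47 ± 0.18 and CDKN1A, an inhibitor of cyclin-dependent kinases, at 1.82 ± 0.31. Matrix genes were lower for 19 of 29 and higher for 0 (21 lower and 3 higher adjusted over the list alone), among them FBN1 at -3.26 ± 0.23 and COL3A1 at -3.49 ± 0.28 (camera adjusted p = 1.36e-25, and adjusted p = 0.232 with an estimated correlation). In the list for epithelial-mesenchymal transition 15 of 27 fell and 0 rose (21 and 0 adjusted over the list alone, camera adjusted p = 1.91e-16, and adjusted p = 0.259 with an estimated correlation). FN1 was at -2.99 ± 0.28 and ZEB1 at -2.50 ± 0.26. The matrix and transition genes moved with the fibroblast markers, of which 14 of 18 fell (17 adjusted over the list alone), and with the fibroblast-like share, whose mean difference was -23.4 points. For migration and matrix proteases 7 of 30 fell and 2 rose (14 and 2 adjusted over the list alone, camera adjusted p = 0.000153, and adjusted p = 0.379 with an estimated correlation).

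Some transcripts that serve as signs of RNA quality and handling differed between the groups as well. Of 7 nuclear-retained transcripts 3 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.347), with MALAT1 at 1.31 ± 0.14, NEAT1 at 1.84 ± 0.34, SNHG14 at 0.67 ± 0.17 and KCNQ1OT1 at -1.33 ± 0.25. Of 13 mitochondrially encoded transcripts 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0770), MT-ND6 at 1.57 ± 0.26 and MT-ATP8 at 0.90 ± 0.22. In the list of heat shock and dissociation stress 6 of 26 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00554, and adjusted p = 0.547 with an estimated correlation), with HSPA1A at 1.23 ± 0.17.

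In all, 2798 of 21143 tested genes differed, 1320 higher and 1478 lower, and 647 of them by at least 4-fold. With the donor as a block the number was 6294. It was 1444, 1462 and 1083 without vehicle library 1, 2 or 3, and 911 and 1092 without octanoic acid library 2 or 3. Leaving out donor 1, 2 or 3 gave 501, 0 and 93, where the 0 from edgeR stood beside 4664 genes at an unadjusted p under 0.05. Without the 2 libraries with most cells in clusters made mostly of the other group it was 259, of which 244 were among the 2798. Of the 141 called genes that the rule or a list named, 72 kept the call without any 1 library, PLIN2, CPT1A, CLGN and COL1A1 among them. GDF15 and MKI67 reached adjusted p of up to 0.0767 and 0.102.

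In basal-like cells under octanoic acid, genes that rose outnumbered those that fell in the lists of PPAR targets, stress responses and EGF receptor signalling, and 6 of 18 basal markers were lower. PLIN2 rose from 14.3 ± 9.73 to 457 ± 224 CPM (SD, n = 3; log2 fold change 4.97 ± 0.62, adjusted p = 0.00562). ANGPTL4, a secreted inhibitor of lipoprotein lipase and a PPAR target, rose from 7.27 ± 2.80 to 129 ± 49.3 (4.14 ± 0.38, adjusted p = 0.00338). GDF15 rose from 16.9 ± 8.97 to 431 ± 230 (4.65 ± 0.58, adjusted p = 0.00560). ACTA2, the smooth muscle actin of myoepithelial cells, fell from 727 ± 478 to 26.5 ± 15.1 (-4.77 ± 0.63, adjusted p = 0.00644). The chemokine CXCL3 rose from 6.43 ± 1.28 to 90.3 ± 25.4 (3.79 ± 0.26, adjusted p = 0.00149).

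Other large changes were rises of the transporter SLCO4A1 (6.09 ± 0.61) and of CLGN (5.28 ± 0.28). Among the falls were those of STRA6, the membrane receptor for retinol-binding protein (-5.62 ± 0.39), of the GABA receptor subunit GABRP (-5.46 ± 0.52) and of the kallikrein protease KLK10 (-4.75 ± 0.44). CPT1A rose by 1.74 ± 0.29 (adjusted p = 0.0113). PHGDH rose by 0.97 ± 0.23 (adjusted p = 0.0343). PSAT1, the next enzyme of that pathway, had a log2 fold change of 0.64 ± 0.18 (adjusted p = 0.0506), and HES1, a target of Notch, one of 0.86 ± 0.25 (adjusted p = 0.0557). With the donor as a block both passed, at adjusted p = 0.0238 and 0.0127. For PDK4, a kinase that restrains pyruvate oxidation, it was -0.59 ± 0.38 (adjusted p = 0.326).

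In these cells 12 of 33 genes of the PPAR list rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 4.82e-05, and adjusted p = 0.110 with an estimated correlation). PPARG itself was at 2.33 ± 0.29. Of 4 adipocyte markers G0S2 rose, at 2.30 ± 0.52 (camera adjusted p = 0.0983). The ATF4 list had 9 of 24 rising and 0 falling (15 and 0 adjusted over the list alone, camera adjusted p = 2.54e-09, and adjusted p = 0.274 with an estimated correlation). ATF3 was at 2.14 ± 0.18 and the cystine transporter SLC7A11 at 1.91 ± 0.27. For NRF2 targets it was 9 of 26 and 0 (14 and 1 adjusted over the list alone, camera adjusted p = 1.04e-06, and adjusted p = 0.196 with an estimated correlation). SRXN1 was at 2.20 ± 0.19 and the glutathione reductase GSR at 1.82 ± 0.22. Glycolysis and hypoxia genes rose for 10 of 28 and fell for 0 (14 and 0 adjusted over the list alone, camera adjusted p = 1.40e-06, and adjusted p = 0.110 with an estimated correlation). The lactate transporter SLC16A3 was at 1.51 ± 0.19. Inflammatory NF-kB targets rose for 8 of 26 and fell for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 6.45e-05, and adjusted p = 0.215 with an estimated correlation). The chemokine CXCL8 was at 2.48 ± 0.30. In the list of EGF receptor ligands and MAPK feedback 8 of 27 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.000453, and adjusted p = 0.215 with an estimated correlation). The ligand AREG was at 2.76 ± 0.45 and the phosphatase DUSP1 at 1.94 ± 0.15.

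Basal markers fell within the class: 6 of 18 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 7.18e-08, and adjusted p = 0.110 with an estimated correlation). Smooth muscle myosin MYH11 was at -3.55 ± 0.28 and caveolin CAV1 at -2.64 ± 0.30. These markers also served to name the clusters, and fewer cells of every library took the basal name when assigned one by one. Keratin and epidermal genes were lower for 8 of 21 and higher for 0 (9 and 0 adjusted over the list alone, camera adjusted p = 8.06e-08, and adjusted p = 0.274 with an estimated correlation). The protease KLK7 was at -4.12 ± 0.48 and KLK6 at -2.56 ± 0.33. Among migration genes 7 of 29 fell and 0 rose (11 and 1 adjusted over the list alone, camera adjusted p = 8.26e-06, and adjusted p = 0.255 with an estimated correlation). The integrin chain ITGAV was at -1.40 ± 0.21 and ITGB6 at -1.71 ± 0.29. Cell division genes fell for 13 of 23 and rose for 0 (16 and 0 adjusted over the list alone, camera adjusted p = 2.54e-09, and adjusted p = 0.274 with an estimated correlation). Of 29 matrix genes 11 fell and 2 rose (17 and 2 adjusted over the list alone, camera adjusted p = 7.18e-08, and adjusted p = 0.274 with an estimated correlation). They moved with the fibroblast markers, 7 of 18 of which fell and 1 rose. Of all genes called lower in this class, 18 could be mostly free RNA in vehicle by the upper estimate. COL3A1, in both lists, is among the genes that set this estimate, which decides nothing for it. Among signs of RNA quality and handling, 1 of 7 nuclear-retained transcripts rose, MALAT1 at 1.15 ± 0.20 (camera adjusted p = 0.432). Of 13 mitochondrially encoded ones 3 rose, with MT-ND6 at 1.80 ± 0.22 (camera adjusted p = 0.0485, and adjusted p = 0.603 with an estimated correlation). Of 25 genes of heat shock and dissociation stress 7 rose (camera adjusted p = 0.00187, and adjusted p = 0.274 with an estimated correlation).

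Altogether 2420 of 16229 tested genes differed in basal-like cells, 1261 higher and 1159 lower, 415 of them by at least 4-fold. It was 4677 with the donor as a block. The number was 805 without vehicle library 3, and 655, 835 and 1051 without octanoic acid library 1, 2 or 3. Leaving out donor 1 or 3 gave 503 and 0 (edgeR, with 3228 genes at an unadjusted p under 0.05 for the latter). It was 952 without the 2 libraries with most cells in clusters of the other group, 838 of them among the 2420. Without any 1 library, 76 of 128 called genes named by the rule or a list kept the call, PLIN2, ANGPTL4, GDF15 and ACTA2 among them. PHGDH reached an adjusted p of up to 0.121.

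Luminal-like cells, which pool the secretory and hormone-sensing classes, had lower levels of most measured cell division transcripts and higher levels of some of those of amino acid stress, protein folding and lipid synthesis. MMP12, a macrophage elastase, averaged 18.1 ± 0.402 CPM in vehicle and 0.111 ± 0.0230 in octanoic acid (SD, n = 3; adjusted p = 0.000241). RRM2, which makes the building blocks of DNA, fell from 38.2 ± 11.4 to 1.26 ± 1.497 (log2 fold change -4.92 ± 0.77, adjusted p = 0.0179). GSTA1, a glutathione transferase, fell from 41.7 ± 2.34 to 0.872 ± 0.780 (-5.60 ± 0.53, adjusted p = 0.00626). TNNT1, a troponin of slow muscle, rose from 2.45 ± 1.91 to 52.99 ± 2.75 (4.50 ± 0.49, adjusted p = 0.00766). The histone gene H2BC4 rose by 3.94 ± 0.40 (adjusted p = 0.00726) and ELOVL4, which lengthens very long fatty acids, by 3.16 ± 0.27 (adjusted p = 0.00601).

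PLIN2 rose from 65.8 ± 51.9 to 422 ± 65.4 (2.69 ± 0.56, adjusted p = 0.0342) and ANGPTL4 by 2.24 ± 0.40 (adjusted p = 0.0242). CPT1A rose by 1.499 ± 0.278 (adjusted p = 0.0255), PHGDH by 1.13 ± 0.19 (adjusted p = 0.0198) and PDK4 by 0.89 ± 0.20 (adjusted p = 0.0412). The hormone-sensing part of the luminal-like cells was 28.9%, 12.1% and 44.3% in the vehicle libraries and 23.7%, 24.8% and 62.4% in the octanoic acid libraries. PDK4 was at 0.19 ± 0.38 (adjusted p = 0.771) in secretory-like cells and at 1.56 ± 0.51 (adjusted p = 0.149, and 0.00197 with the donor as a block) in hormone-sensing-like cells, where its level was higher (150.9 and 445.9 CPM, against 65.8 and 75.5). The effect of this mix on the pooled value was not tested. PSAT1 had a log2 fold change of 0.82 ± 0.21 (adjusted p = 0.0557, and 0.0474 with the donor as a block) and HES1 one of -0.02 ± 0.17 (adjusted p = 0.955). For HES1 it was 0.19 ± 0.15 (adjusted p = 0.448) in secretory-like and -0.77 ± 0.27 (adjusted p = 0.152, and 0.0212 with the donor as a block) in hormone-sensing-like cells. Without any 1 library, adjusted p reached 0.0942 for PLIN2, 0.0721 for ANGPTL4, 0.0825 for CPT1A, 0.0815 for PHGDH and 0.114 for PDK4.

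Of 31 measured cell division genes 26 fell and 0 rose (31 and 0 adjusted over the list alone), among them MCM3 at -1.48 ± 0.14 and the mitotic cyclin CCNB1 at -3.06 ± 0.31. The camera adjusted p was 1.92e-43, and the adjusted p = 0.180 with an estimated correlation. The ATF4 list had 11 of 24 rising and 0 falling (15 and 0 adjusted over the list alone, camera adjusted p = 1.02e-11, and adjusted p = 0.0558 with an estimated correlation). SLC7A11 was at 2.11 ± 0.15 and SLC3A2 at 1.25 ± 0.16. In the list of the unfolded protein response and endoplasmic reticulum chaperones 7 of 20 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 3.32e-06, and adjusted p = 0.140 with an estimated correlation). EDEM1, which sends misfolded proteins to degradation, was at 1.36 ± 0.13 and the co-chaperone DNAJB9 at 1.26 ± 0.18. Cholesterol genes rose for 5 of 22 and fell for 0 (7 and 0 adjusted over the list alone, camera adjusted p = 3.67e-06, and adjusted p = 0.515 with an estimated correlation). STARD4 was at 2.67 ± 0.21 and INSIG1 at 1.64 ± 0.24. Genes of fatty acid synthesis rose for 4 of 19 and fell for 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00155, and adjusted p = 0.392 with an estimated correlation). The desaturase SCD was at 2.36 ± 0.32.

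Among PPAR targets and oxidation genes in luminal-like cells 6 of 32 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.00181, and adjusted p = 0.392 with an estimated correlation). ACSL1 was at 1.63 ± 0.15 and HADH, an enzyme of fatty acid oxidation, at -0.84 ± 0.16. Of 4 adipocyte markers 2 rose, PLIN4 at 1.60 ± 0.35 and CIDEA at 1.88 ± 0.45 (camera adjusted p = 0.0415, and adjusted p = 0.402 with an estimated correlation). NRF2 targets rose for 7 of 26 and fell for 0 (8 and 0 adjusted over the list alone, camera adjusted p = 2.92e-05, and adjusted p = 0.128 with an estimated correlation). The heme oxygenase HMOX1 was at 1.65 ± 0.25. Of 28 matrix genes 5 fell and 1 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.00137, and adjusted p = 0.515 with an estimated correlation). They moved with the fibroblast markers, 4 of 18 of which fell. Of all genes called lower in luminal-like cells, 11 could be mostly free RNA in vehicle by the upper estimate. Among signs of RNA quality and handling, 2 of 7 nuclear-retained transcripts rose, MALAT1 at 0.97 ± 0.17 and NEAT1 at 1.85 ± 0.33 (camera adjusted p = 0.136). Of 13 mitochondrially encoded ones 1 rose, MT-ND6 at 1.62 ± 0.28, and 1 fell, MT-CYB at -0.70 ± 0.16 (camera adjusted p = 0.598). Of 26 genes of heat shock and dissociation stress 4 rose and 2 fell (camera adjusted p = 0.244).

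Over the whole transcriptome 1602 of 17244 tested genes differed in luminal-like cells, 797 higher and 805 lower, 368 of them by at least 4-fold. It was 4580 with the donor as a block. The number was 758, 941 and 214 without vehicle library 1, 2 or 3, and 313, 685 and 406 without octanoic acid library 1, 2 or 3. Without donor 1, 2 or 3 it was 1, 364 and 0 (edgeR, with 2812 genes at an unadjusted p under 0.05 for the 0). Without the 2 libraries with most cells in clusters of the other group it was 322, 287 of them among the 1602. Of 112 called genes named by the rule or a list, 25 kept the call without any 1 library, MMP12, GSTA1, TNNT1 and H2BC4 among them. RRM2 reached an adjusted p of up to 0.0681.

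In fibroblast-like cells under octanoic acid, genes that rose outnumbered those that fell in the lists of PPAR targets and inflammation, and the reverse held for matrix, migration and, for 9 of 28 genes, Notch signalling. PLIN2 rose from 191 ± 66.7 to 1442 ± 325 CPM (SD, n = 3; log2 fold change 2.92 ± 0.29, adjusted p = 0.000948), and FABP4, a fatty acid carrier of fat cells, by 4.04 ± 0.40 (adjusted p = 0.00118). The metallothionein MT1H, which binds zinc and copper, rose from 0.803 ± 0.369 to 81.6 ± 62.4 (6.55 ± 0.67, adjusted p = 0.00138). PDK4 rose from 8.86 ± 1.16 to 71.3 ± 41.9 (3.00 ± 0.41, adjusted p = 0.00334). COL1A1 fell from 5768 ± 65.1 to 565 ± 460 (-3.35 ± 0.53, adjusted p = 0.00567). COL7A1, the anchoring collagen, fell from 133 ± 16.2 to 19.3 ± 3.76 (-2.82 ± 0.18, adjusted p = 0.000171).

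CPT1A rose by 1.60 ± 0.22 (adjusted p = 0.00265) and ANGPTL4 from 177 ± 24.1 to 422 ± 79.6 (1.25 ± 0.18, adjusted p = 0.00265). CLGN (4.89 ± 0.45), the amino acid transporter SLC6A15 (4.97 ± 0.53) and SNAP25, a protein of vesicle release (4.93 ± 0.66), were also higher, while the adhesion protein CDH2 (-3.10 ± 0.44) was lower. PHGDH, PSAT1 and HES1 had log2 fold changes of 0.16 ± 0.16, -0.21 ± 0.13 and -0.09 ± 0.19 (adjusted p = 0.503, 0.282 and 0.752).

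The PPAR and oxidation list had 16 of 33 genes rising and 1 falling (17 and 1 adjusted over the list alone, camera adjusted p = 3.01e-06, and adjusted p = 0.0944 with an estimated correlation). PPARG was at 1.62 ± 0.18 and HADHB, part of the mitochondrial oxidation complex, at 0.99 ± 0.13. Of 3 adipocyte markers 1 rose, FABP4, which is also in the PPAR list (camera adjusted p = 0.0707). Cholesterol genes rose for 9 of 22 and fell for 0 (10 and 0 adjusted over the list alone, camera adjusted p = 5.23e-05, and adjusted p = 0.366 with an estimated correlation). DHCR7 was at 2.49 ± 0.26. NF-kB targets rose for 12 of 29 and fell for 2 (15 and 2 adjusted over the list alone, camera adjusted p = 9.19e-06, and adjusted p = 0.0944 with an estimated correlation). ICAM1 was at 1.84 ± 0.20 and SOD2 at 1.98 ± 0.23. NRF2 targets rose for 12 of 25 and fell for 3 (12 and 3 adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.243 with an estimated correlation). The ferritin chain FTH1 was at 1.49 ± 0.15 and the reductase AKR1C1 at 2.93 ± 0.32. In the ATF4 list 6 of 24 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.616), with ATF3 at 1.41 ± 0.19 and the amino acid transporter SLC7A5 at -1.33 ± 0.17.

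Endoplasmic reticulum chaperone genes fell in this class for 6 of 20 and rose for 0 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00650, and adjusted p = 0.347 with an estimated correlation). The protein-folding enzyme PDIA3 was at -0.72 ± 0.14 and calreticulin CALR at -0.71 ± 0.14. In the Notch list 9 of 28 fell and 2 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.00650, and adjusted p = 0.158 with an estimated correlation). The receptor NOTCH1 was at -1.34 ± 0.16, NOTCH3 at -1.33 ± 0.17 and the target HEYL at -2.13 ± 0.27. Of 29 matrix genes 16 fell and 0 rose (16 and 0 adjusted over the list alone, camera adjusted p = 1.26e-09, and adjusted p = 0.158 with an estimated correlation). COL6A1 was at -1.22 ± 0.14. The transition list had 12 of 27 falling and 3 rising (15 and 3 adjusted over the list alone, camera adjusted p = 0.000105, and adjusted p = 0.158 with an estimated correlation). SPARC was at -2.36 ± 0.28. Migration genes fell for 14 of 29 and rose for 1 (16 and 3 adjusted over the list alone, camera adjusted p = 3.13e-05, and adjusted p = 0.347 with an estimated correlation). The actin crosslinker ACTN1 was at -1.51 ± 0.14 and the protease PLAU at -1.51 ± 0.20. These 3 lists moved with the fibroblast markers, 11 of 18 of which fell and 1 rose within the class. Some transcripts that serve as signs of RNA quality and handling differed in this class as well. Of 7 nuclear-retained transcripts 3 rose and 2 fell (camera adjusted p = 0.104), with MALAT1 at 1.42 ± 0.19, NEAT1 at 1.87 ± 0.29, SNHG14 at 1.10 ± 0.20 and NORAD at -0.65 ± 0.14. Of 13 mitochondrially encoded ones 3 rose (camera adjusted p = 0.104), with MT-ND5 at 1.14 ± 0.26, MT-ATP8 at 0.90 ± 0.22 and MT-ND6 at 0.92 ± 0.24. Of 25 genes of heat shock and dissociation stress 8 rose and 1 fell (camera adjusted p = 0.00650, and adjusted p = 0.451 with an estimated correlation), HSPA1A at 1.78 ± 0.15 and HSPA1B at 1.57 ± 0.22.

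**Figure D3:**
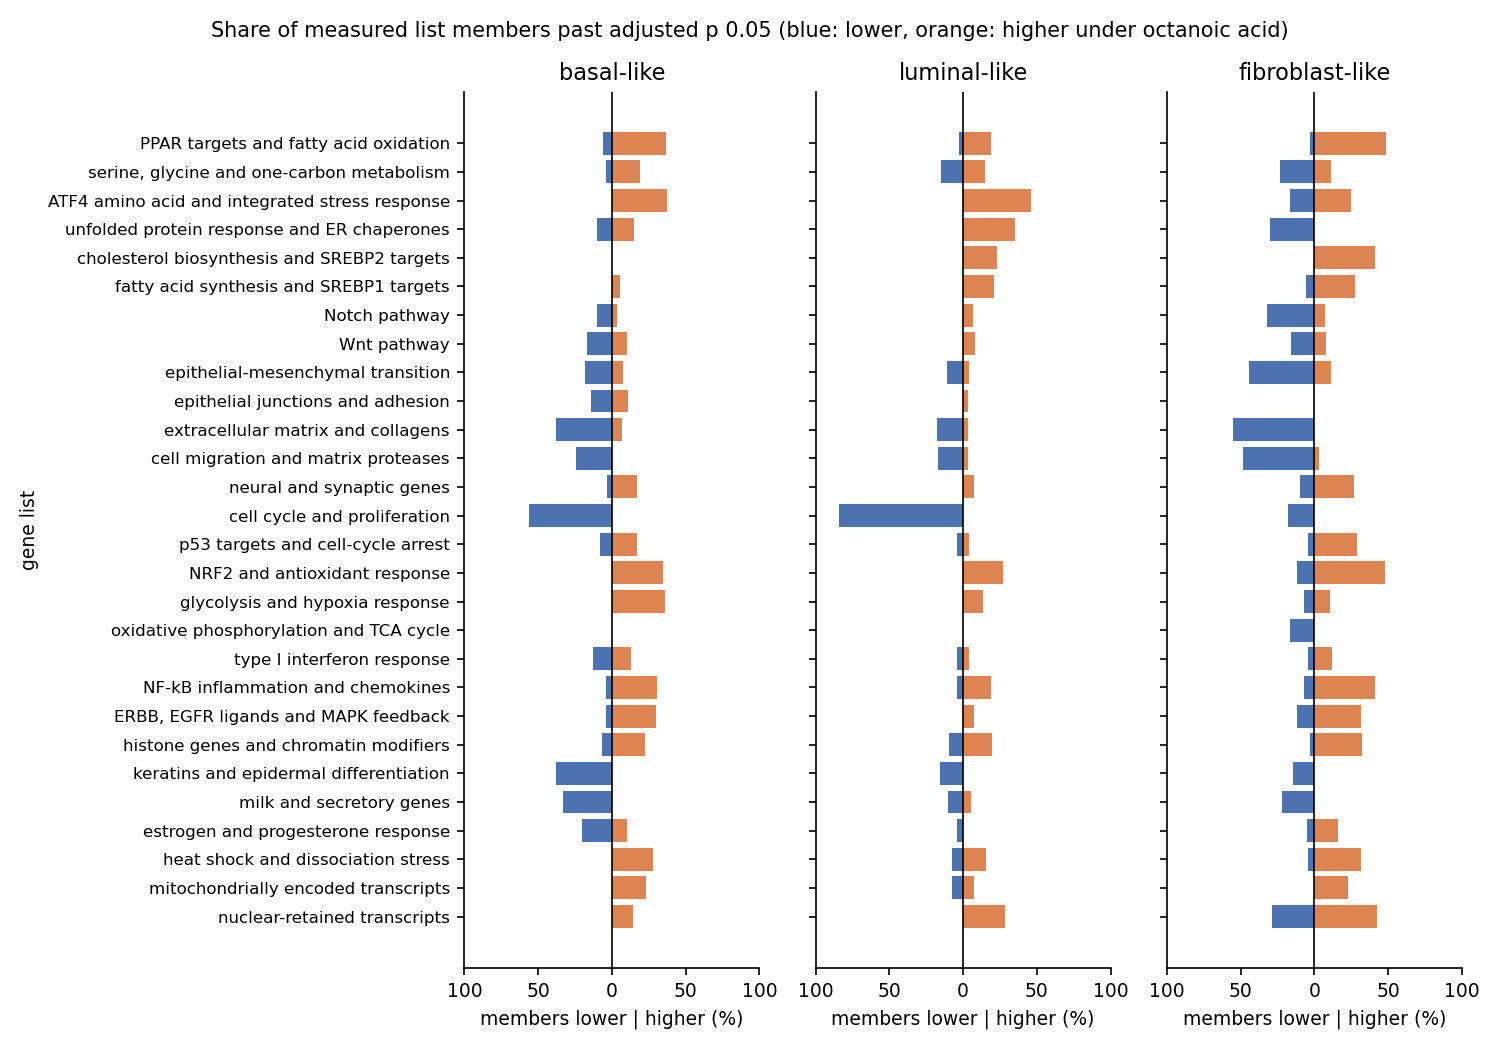
Share (%) of the measured members of each of the 28 gene lists with an adjusted p under 0.05, in basal-like, luminal-like and fibroblast-like cells, with lower members in blue to the left and higher ones in orange to the right. Cell division members are lower for 26 of 31 in luminal-like cells, and PPAR and oxidation members higher for 16 of 33 in fibroblast-like cells.

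Counted over all tested genes, 3421 of 15386 differed in fibroblast-like cells, 1871 higher and 1550 lower, 475 of them by at least 4-fold. It was 4844 with the donor as a block. The number was 2193 without vehicle library 3, 1435 and 1991 without octanoic acid library 1 or 3, and 697 and 652 without donor 1 or 3. It was 1945 without the 2 libraries with most cells in clusters of the other group, 1696 of them among the 3421, and 2254 with the same number of cells from every library. Of 130 called genes named by the rule or a list, 103 kept the call without any 1 library, PLIN2, PDK4, FABP4, MT1H and COL1A1 among them. Among all 3421 genes called in this class, 23 could be mostly free RNA by the upper estimate, 12 of them lower under octanoic acid.

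Whether a gene responded alike in different classes was tested by the class-by-treatment term, which asks whether the log2 fold change in 1 class differs from that in another. PDK4 had its largest log2 fold change in fibroblast-like cells, above that of basal-like cells by 3.46 ± 0.56 (adjusted p = 0.0174). It was above that of luminal-like cells by 1.93 ± 0.42 (adjusted p = 0.0448), which pool secretory-like (0.19) and hormone-sensing-like cells (1.56). The vehicle level of PDK4 was lowest in fibroblast-like cells, at 8.86 CPM, against 24.1 in basal-like and 86.7 in luminal-like cells. Under octanoic acid its level was highest in luminal-like cells (161, against 71.3 in fibroblast-like and 16.1 in basal-like cells). ANGPTL4 had its largest log2 fold change in basal-like cells. The term was -1.75 ± 0.28 for luminal-like (adjusted p = 0.0391) and -2.88 ± 0.38 for fibroblast-like cells (adjusted p = 0.00786). Its vehicle level was lowest in basal-like cells, at 7.27 CPM, against 14.5 in luminal-like and 177 in fibroblast-like cells. Under octanoic acid its level was still highest in fibroblast-like cells (422, against 129 in basal-like and 69.0 in luminal-like cells). PHGDH and PSAT1 had lower fold changes in fibroblast-like than in basal-like cells (-0.86 and -0.88, adjusted p = 0.00807 and 0.00738) and than in luminal-like cells (-1.01 and -1.10, adjusted p = 0.00529 and 0.0200). The term for CPT1A did not pass the threshold in any of the 3 pairs (-0.22, -0.17 and 0.05, adjusted p = 0.474, 0.519 and 0.881).

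**Figure D4:**
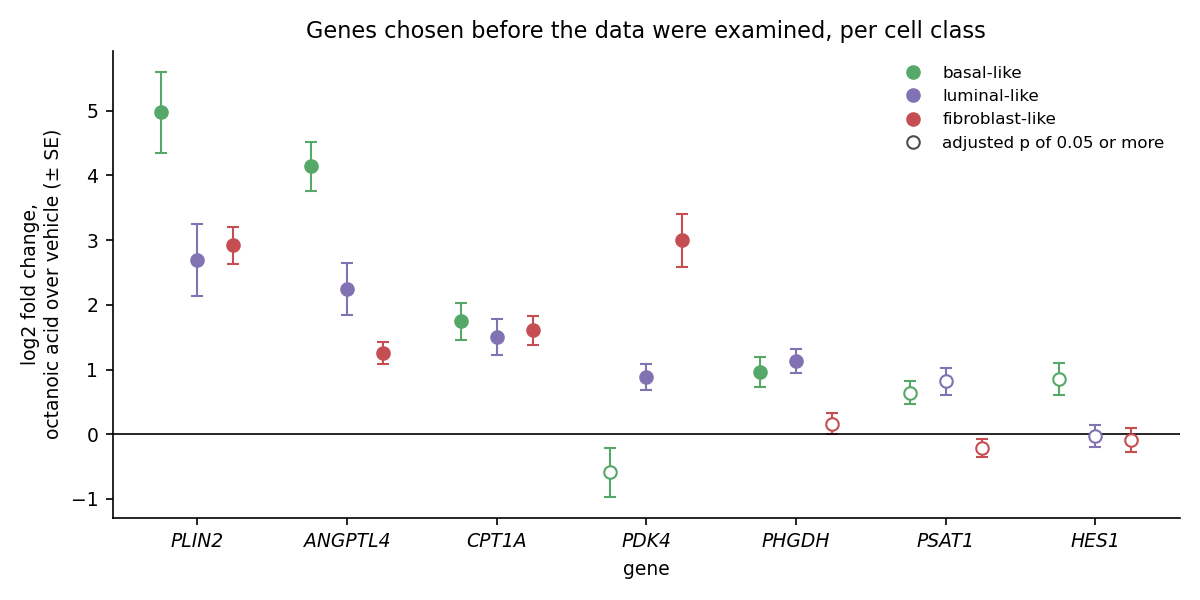
Log2 fold change (octanoic acid over vehicle, ± SE) of 7 genes chosen in advance, in basal-like, luminal-like and fibroblast-like cells, with open points at an adjusted p of 0.05 or more. PDK4 is at -0.59 in basal-like and 3.00 in fibroblast-like cells, and ANGPTL4 at 4.14 and 1.25.

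Genes of the unfolded protein response, of the ATF4 list and of serine metabolism responded differently in fibroblast-like and in epithelial cells. Of 20 genes of the unfolded protein response, 17 differed between luminal-like and fibroblast-like cells and all 17 had the lower fold change in fibroblast-like cells (camera on the term, adjusted p = 7.3e-17, and adjusted p = 0.182 with an estimated correlation). Between basal-like and fibroblast-like cells 7 of 20 differed, all 7 lower in fibroblast-like cells (camera adjusted p = 1.08e-05, and adjusted p = 0.361 with an estimated correlation). The list also parted the epithelial classes, with 3 genes of higher fold change in luminal-like than in basal-like cells (camera adjusted p = 1.86e-06, and adjusted p = 0.464 with an estimated correlation). HERPUD1, which acts in protein degradation at the endoplasmic reticulum, had a log2 fold change of 0.80 in luminal-like and of -0.59 in fibroblast-like cells (term -1.46, adjusted p = 0.00511). Of 24 ATF4 genes 12 differed in each of the pairs with fibroblast-like cells, all 12 lower than in basal-like cells and 11 lower than in luminal-like cells (camera adjusted p = 7.88e-11 and 1.41e-07, and adjusted p = 0.361 and 0.187 with an estimated correlation). Serine and one-carbon genes differed for 10 of 27 in both pairs, 9 of them lower in fibroblast-like cells (camera adjusted p = 5.24e-05 and 0.00266, and adjusted p = 0.361 and 0.182 with an estimated correlation). The heat shock and dissociation stress list did not follow. Of its 26 genes 6 responded more and 1 less in fibroblast-like than in luminal-like cells (camera adjusted p = 0.0270, and adjusted p = 0.674 with an estimated correlation), and 3 more and 3 less than in basal-like cells (camera adjusted p = 0.949).

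**Figure D5:**
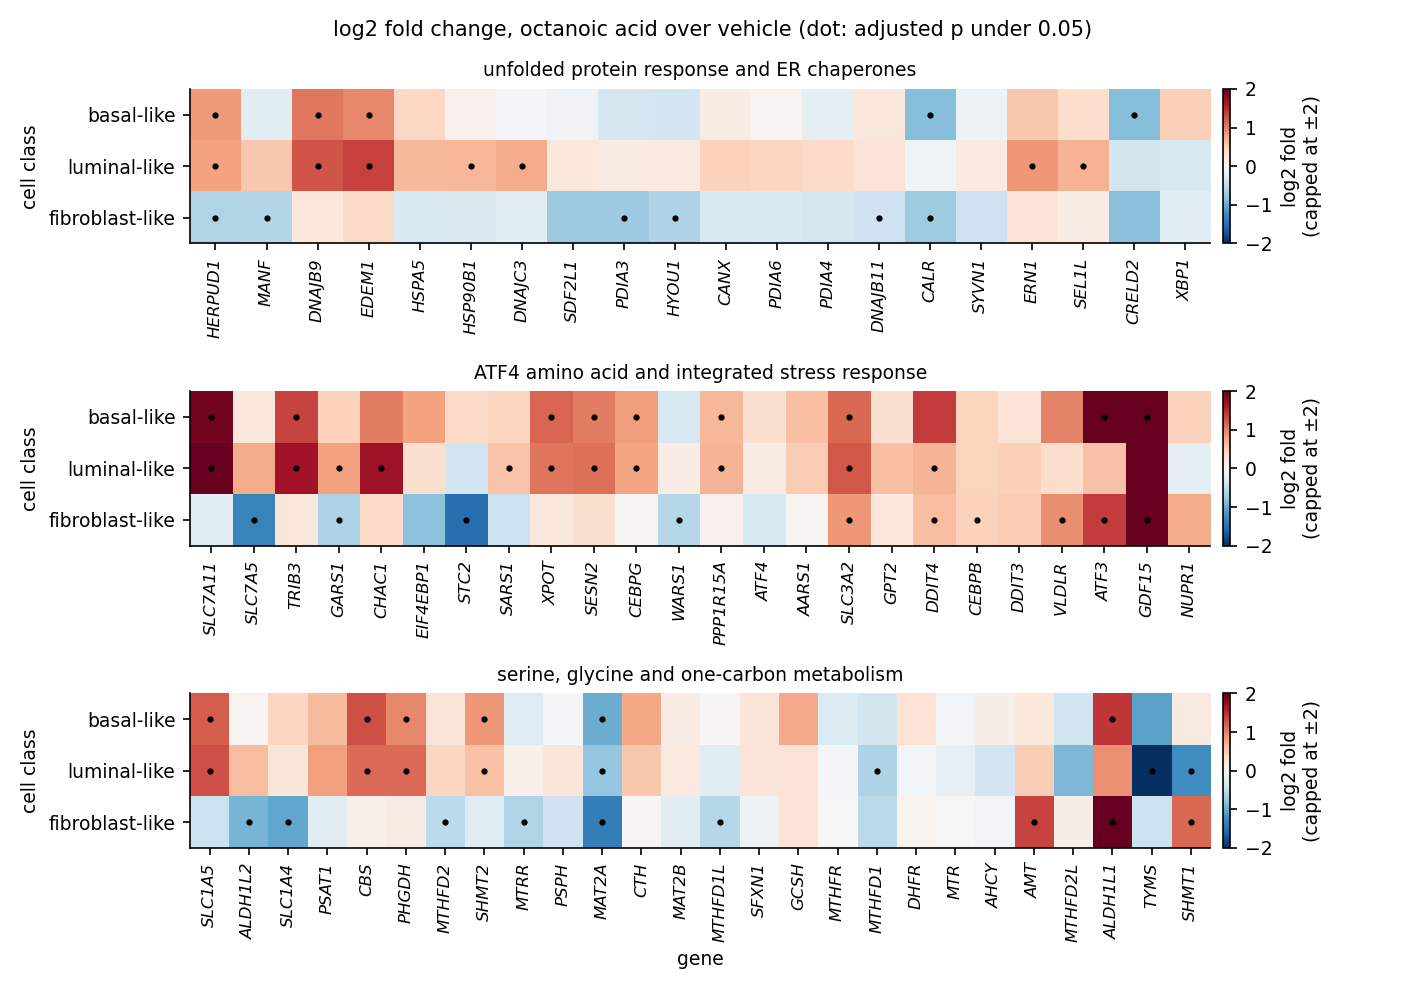
Log2 fold change (octanoic acid over vehicle, colours end at -2 and 2) of genes in 3 lists, in basal-like, luminal-like and fibroblast-like cells, with a dot at an adjusted p under 0.05. Of the 20 unfolded protein response genes, 17 have a lower fold change in fibroblast-like than in luminal-like cells by the class-by-treatment test.

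Responses differed for 197 of 18293 genes between basal-like and luminal-like cells. Between basal-like and fibroblast-like cells they differed for 1937 of 17250, and between luminal-like and fibroblast-like cells for 1400 of 18604. Without donor 1, 2 or 3 the first number was 0, 4 and 0 (edgeR, with 2106 and 2021 genes at an unadjusted p under 0.05 for the 0 values). The second number was 390, 1474 and 78, and the third 69, 1158 and 64. Among these, genes that were called in both classes with opposite signs numbered 4, 41 and 29.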

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

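The comparisons of the classes by the class-by-treatment term were planned, while the count of other splits for changed genes, the test of a fixed count floor and the tests of free RNA were chosen after the results were seen.

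The response of 197 genes differed between basal-like and luminal-like cells. ANGPTL4 rose less in luminal-like cells (term -1.75 ± 0.28, adjusted p = 0.0391). The 4 genes called in both classes with opposite signs, named for that reason after their values were seen, were GUCY1B1, a subunit of the nitric oxide receptor (-2.44 in basal-like and 1.43 in luminal-like cells, term 3.90), E2F7, a repressor of cell cycle genes (1.57 and -2.65, term -4.15), LRRC8A, a part of volume-regulated anion channels (-0.72 and 0.77, term 1.52), and NEURL1B (1.59 and -1.45, term -3.002).

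Between basal-like and fibroblast-like cells the response of 1937 genes differed. PDK4 was at -0.59 in basal-like and 3.00 in fibroblast-like cells (term 3.46), ANGPTL4 at 4.14 and 1.25 (term -2.88), and PLIN2 at 4.97 and 2.92 (term -2.10). HES1 had a term of -1.01, PHGDH of -0.86 and PSAT1 of -0.88, with the lower fold change in fibroblast-like cells. The same direction held for SLC1A5, a glutamine transporter (-1.68), SHMT2, a mitochondrial one-carbon enzyme (-1.12), SLC7A5 (-1.59), the glycyl-tRNA ligase GARS1 (-1.10), SRXN1 (-1.16), SLC7A11 (-2.12), the vessel growth factor VEGFA (-1.72) and PFKFB4 (-2.02). In the Wnt list 9 of 29 differed, 6 with the higher and 3 with the lower fold change in fibroblast-like cells. Among the 6, TCF7L1 had a term of 1.73 and SFRP1 of 0.95.

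Luminal-like and fibroblast-like cells differed in the response of 1400 genes. PDK4 had a term of 1.93, PHGDH of -1.01, PSAT1 of -1.10, SLC1A5 of -1.79, SLC7A5 of -2.19 and SLC7A11 of -2.39. The chaperone HSP90B1 was at 0.67 in luminal-like and -0.29 in fibroblast-like cells (term -1.01), and HERPUD1 at 0.80 and -0.59 (term -1.46). In the matrix list COL6A1 was at 0.46 and -1.22 (term -1.78) and COL4A2 at -1.95 and -0.16 (term 1.73).

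The 10 splits of the 6 libraries into 3 and 3 were too few for a share under 0.05. Every other split also put libraries of both treatments in each group, so a treatment difference widened the spread within its groups. Low numbers of genes in the other splits were thus partly set by the design and are no rate of false calls. For changed genes, 1.0 split, the real one, gave a number as large in each of the 6 comparisons, with 2798, 2420, 1602, 3421, 2464 and 256 genes for all, basal-like, luminal-like, fibroblast-like, luminal secretory-like and luminal hormone-sensing-like cells, and the highest other split called 0 genes in each (edgeR, with up to 1285, 843, 1287, 723, 907 and 941 at an unadjusted p under 0.05). These highest unadjusted numbers came from splits that part 1 of the 3 donor pairs. Other splits that part all 3, as the real one does, reached at most 158, 99, 163, 361, 162 and 384. The class-by-treatment counts of 197, 1937 and 1400 stood beside 1, 0 and 0 for the highest other split. For the last 2, up to 993 and 1038 genes were at an unadjusted p under 0.05 in other splits (edgeR). For the number of lists called by camera, the splits as large numbered 2.0, 1.0, 2.0, 3.0, 3.0 and 2.0 in the same order of comparisons, with 20, 19, 15, 17, 15 and 16 lists in the real split and 22, 17, 17, 22, 15 and 16 in the highest other. Except in basal-like cells, another split thus called as many lists or more. The number of lists called at the preset correlation therefore does not set the treatment apart from other groupings there.

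Some cells lay in clusters of which at least 90% came from the other group. In vehicle library 1 these were 299 of 8150 cells (3.67%), in octanoic acid library 2 they were 364 of 6459 (5.64%), and in the other libraries 0.12% to 0.98%. In vehicle library 1, 1 such cluster held 94 of its 365 hormone-sensing-like cells. In octanoic acid library 2, 1 held 138 of its 831 fibroblast-like cells. PLIN2 in hormone-sensing-like cells was at 367.3 CPM in vehicle library 1 and at 22.39 and 14.43 in vehicle libraries 2 and 3. COL1A1 in fibroblast-like cells was at 1095 in octanoic acid library 2 and at 328 and 271.8 in octanoic acid libraries 1 and 3. Barcodes shared with a library of the other group, as reads assigned to the wrong library would give, were found for at most 0.0% of such cells in the vehicle library and 0.27% in the octanoic acid library, which argues against that source. Placement of shallow cells by few counts is argued against in the octanoic acid library, where these cells had 1.192 times the median count of its other cells, and cannot be told apart in the vehicle library, where the ratio was 0.72 and shallow cells of either origin would give the same. Cells that respond little to the fatty acid, or that respond in the same way without it, may account for them and were not tested, nor was mixing of cells during handling.

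The fibroblast-like share was lower under octanoic acid in all 3 donors. The count threshold set per library is argued against as the whole cause, since with the same floor in every library the share was still lower in all 3 donors, with a mean difference of -11.61 percentage points. That is less than the -23.4 points with the threshold, and the groups then overlapped (exact p = 0.2), so the threshold stays open as part of the cause. A loss of shallow fibroblast-like cells below every count floor stays open: their share at 1000 to 1500 counts exceeded that at higher counts by at least 4.76 points in each octanoic acid library, while in each vehicle library it was lower by at least -9.28 points. Fewer fibroblasts leaving the tissue, or fewer surviving, may also contribute, and neither was tested. Part of the smaller share may thus be one of RNA content and not of cell number.

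Some fibroblast markers were lower in basal-like and luminal-like cells under octanoic acid. Of the 11 markers that do not set the estimate of free RNA, 7 had a lower level in basal-like cells and 4 a higher one, CFD (2.603), LOX (1.177), TWIST2 (0.965) and SFRP2 (0.215). Free RNA from fibroblasts is argued against as the whole cause for the 7, since its upper estimate in vehicle came to a median of 24.8% of their fall (SD 31.5). The least covered were THY1, which fell from 97.79 to 27.55 CPM, and FBLN1, from 33.88 to 13.28, where the estimate allowed 3.41 and 1.37. The most covered were POSTN, to 86.7% of its fall, and PDGFRA, to 71.9%. In luminal-like cells the median over 8 such markers was 144.9% with an SD of 134.8, so free RNA and a lower level in the cells cannot be told apart there, as several of the falls were small. For the 7 genes that set the estimate, COL1A1, COL1A2 and COL3A1 among them, coverage follows from its definition and decides nothing.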

How the results depend on the processing

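Chosen after the data were seen were automatic doublet calls, fixed floors, Leiden resolutions 0.5 and 2 for gene tests and leaving out the 2 libraries with most cells in clusters of the other group. Over all alternatives, 12912 values of named or listed genes kept direction and side of the threshold, 2945 fell short of it, 87 newly passed it and 19 reversed. For differences between classes these numbers were 686, 485, 2 and 7, and for lists 492, 141, 28 and 5. These totals mix alternatives of unlike weight. With DESeq2 size factors 99.9% of the gene values kept both, but without donor 1, 2 or 3 only 40.3%, 59.2% and 16.1% did. For differences between classes it was 27.5%, 61.4% and 11.9% without donor 1, 2 or 3. The count filter left 12520 genes to test in hormone-sensing-like cells and 15386 to 21143 in the other comparisons, and endothelial-like cells were too few to test. The cause was not tested for any change below.

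With the donor as a block, changed genes numbered 6294 in all, 4677 in basal-like, 4580 in luminal-like, 5065 in secretory-like and 1831 in hormone-sensing-like cells. DESeq2 gave 4514, 2837 and 766 for all, luminal-like and hormone-sensing-like cells, and 5986, 3659 and 961 with the block. In the simulated data of all cells, 63 of 197 DESeq2 calls, and 89 of 222 with the block, were of unchanged genes. Without the 2 libraries named above the numbers were 259 (all), 952 (basal-like), 322 (luminal-like), 1945 (fibroblast-like) and 1409 (secretory-like). The same number of cells gave 2254 in fibroblast-like and 116 in hormone-sensing-like cells, where no filter gave 1315, automatic doublets 397 and cells assigned one by one 698. For class-by-treatment, no filter gave 1076 (basal-like against luminal-like) and 3128 (basal-like against fibroblast-like). Lists called numbered 0 in each comparison with an estimated correlation (camera, with 6, 8, 5, 7, 7 and 4 at an unadjusted p under 0.05), and by fry 11 in all, 9 in luminal-like and 6 in hormone-sensing-like cells.

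Leaving out 1 library or 1 donor, changed genes ranged from 0 to 1917 in all, 0 to 2649 in basal-like, 0 to 941 in luminal-like, 652 to 3956 in fibroblast-like, 1 to 2246 in secretory-like and 0 to 733 in hormone-sensing-like cells. Class-by-treatment counts, fitted again only without a donor and not without a single library, ranged from 0 to 4, 78 to 1474 and 64 to 1158. Log2 fold changes that turned ranged from -0.251 to 0.016 (HES1, fibroblast-like), -0.149 to 0.11 (HES1, luminal-like) and -0.05 to 0.638 (PDK4, secretory-like). Class-by-treatment terms that turned were CPT1A (-0.274 to 0.015 for basal-like against fibroblast-like, -0.091 to 0.257 for luminal-like against fibroblast-like), HES1 (-0.208 to 0.01) and PLIN2 (-0.592 to 0.502) for the latter pair, and PHGDH (-0.122 to 0.325) and PSAT1 (-0.184 to 0.459) for basal-like against luminal-like cells.

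Reversals elsewhere were these. The secretory-like share difference was 0.566 points at Leiden resolution 0.5 and 1.885 with doublets kept, the endothelial-like 2.494 with cells assigned one by one, and that of unnamed clusters -0.09 with fixed floors, -1.341 at resolution 0.5 and -6.071 with doublets kept. HES1 in fibroblast-like cells was 0.361 with doublets kept, 0.319 with automatic calls, 0.075 one by one, 0.16 at resolution 2 and 0.11 without the 2 libraries, where HES1 in luminal-like cells was 0.126 and PDK4 in secretory-like cells -0.242. In fibroblast-like cells KRT81 was 0.052 and MYLK 0.834 with doublets kept, and MYLK 0.798 with automatic calls and 0.123 at resolution 2. CPT1A had a term of -0.017 without a filter (luminal-like against fibroblast-like). Lists turned in direction with the block in camera at p of 0.9428 (serine, all cells), 0.8991 (hormone-sensing markers, all cells), 0.7798 (endothelial markers, basal-like) and 0.8231 (macrophage markers, luminal-like), and by fry at 0.9983 (keratins, secretory-like).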

Other observations

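The parts of this section on the 2 luminal classes follow the tests chosen in advance, and the counts without 2 libraries were chosen after the data were seen.

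In luminal secretory-like cells 2464 of 16020 tested genes differed, 1288 higher and 1176 lower, and 5065 with the donor as a block. TNNT1 rose from 1.40 ± 0.252 to 51.2 ± 3.15 CPM (SD, n = 3; log2 fold change 5.24 ± 0.18, adjusted p = 8.27e-05). PRSS3, a trypsinogen, rose by 4.27 ± 0.22 (adjusted p = 0.00105) and PLIN2 by 2.14 ± 0.24 (adjusted p = 0.00446). Of 31 cell division genes 29 fell and 0 rose (31 and 0 adjusted over the list alone, camera adjusted p = 2.54e-34, and adjusted p = 0.240 with an estimated correlation). Thymidylate synthase TYMS was at -3.30. ATF4 targets rose for 11 of 24 and fell for 0 (15 and 0 adjusted over the list alone, camera adjusted p = 2.62e-11, and adjusted p = 0.240 with an estimated correlation). SLC7A11 was at 2.34 and CHAC1, which breaks down glutathione, at 2.05. In the unfolded protein response 9 of 20 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 7.05e-07, and adjusted p = 0.224 with an estimated correlation). DNAJB9 was at 1.43 and HERPUD1 at 0.96. Markers of the class itself fell for 5 of 18 and rose for 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00477, and adjusted p = 0.240 with an estimated correlation). PIGR, the receptor that carries antibodies into milk, was at -2.43 and the receptor KIT at -2.81. The number of changed genes was 1595 and 844 without vehicle library 1 or 3, and 995 and 737 without octanoic acid library 1 or 3. It was 231 and 1 without donor 1 or 3, and 1409 without the 2 libraries with most cells in clusters of the other group, 1157 of them among the 2464.

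In luminal hormone-sensing-like cells 256 of 12520 tested genes differed, 133 of them lower, and 1831 with the donor as a block. TFF1, a classical estrogen target, fell from 1253 ± 663 to 26.6 ± 21.1 CPM (SD, n = 3; -5.43 ± 0.71, adjusted p = 0.0284), and the chemokine CCL2 from 50.6 ± 31.5 to 0.544 ± 0.643 (-5.70 ± 0.76, adjusted p = 0.0284). In the list of the estrogen and progesterone response 3 of 23 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 5.87e-08, and adjusted p = 0.479 with an estimated correlation). The pioneer factor FOXA1 was at -1.38 ± 0.17 and cyclin CCND1 at -2.16. Markers of the class fell for 2 of 18 (8 adjusted over the list alone, camera adjusted p = 1.76e-07, and adjusted p = 0.479 with an estimated correlation). ATF4 targets rose for 4 of 23 (11 adjusted over the list alone), with SLC7A11 at 1.45 and TRIB3 at 1.38 (camera adjusted p = 9.17e-08, and adjusted p = 0.384 with an estimated correlation), and cell division genes fell for 11 of 18 (15 adjusted over the list alone, camera adjusted p = 3.87e-24, and adjusted p = 0.384 with an estimated correlation). The number of changed genes was 733 without vehicle library 1, 0 without vehicle library 3 or any 1 of the octanoic acid libraries, and 81, 22 and 0 without donor 1, 2 or 3. The 0 values came from edgeR and stood beside 1812, 2148, 1972 and 2221 genes at an unadjusted p under 0.05 for the single libraries and 1312 for donor 3. Of 47 called genes named by the rule or a list, 0 kept the call in each fit without 1 library, and the adjusted p reached 0.120 for TFF1 and for CCL2.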
